A study of Mus musculus with 13 samples.

How the data were processed

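CUT&RUN (cleavage under targets and release using nuclease, in which a nuclease tethered to an antibody cuts chromatin at the bound places) was read out in 13 libraries of mouse embryonic fibroblasts that carried a lentiviral, doxycycline-inducible Myf6 with an HA tag. The cells had spent 24 h in a medium that the labels call iMPC medium, under 1 of 3 treatments. For each treatment there were 2 libraries with an antibody against the HA tag and 2 with a control IgG. A single library with an antibody against H3K27me3, a histone mark of Polycomb-repressed chromatin, served as the positive control of the assay and came from the cells with Myf6 and the 3 compounds. Per the labels' protocols, each reaction started from 500000 cells with 5000 Drosophila nuclei as spike-in, and the HA and IgG reactions of a replicate were divided from the same nuclei. Spike-in reads were not used here.

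The deposited files were lists of narrow peaks, 1 list per library, so replicates were called separately and not pooled. Per the submitters' processing notes, deepTools, MACS2 and DiffBind were used and the genome build was GRCm39. Their versions and the aligner are not given in the sources used here. Each line held an interval, the position of its summit, a fold enrichment at the summit (a ratio to the local background, as deposited by the authors), and the −log10 of a p-value and of a q-value for the summit, also as deposited. The lowest −log10 q in any list was 1.30, and the lists held no interval more than once. No 2 lists were identical. These scores belong to their own list and were used only to describe, rank or filter peaks within it, and no model of differential signal was fitted.

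Peaks were counted on chromosomes 1 to 19, X and Y. The depth of each library was recovered from its list. With the fold taken as (k + 1)/(λ + 1) and the p-value as a Poisson tail of k given λ, whole summit pileups k and expected pileups λ matched the deposited −log10 p to within 0.002 for at least 99.9% of the peaks of every list. In every list, each expected pileup above the list's lowest one and under 2 was a whole number of fragments in a window of 10 kb, to within 0.05 of a fragment, when the fragment length was set to the width of the list's narrowest peak. The lists therefore hold the background of the library's own 10 kb windows, and the lowest expected pileup gives the mean number of fragments per 10 kb. This mean ran from 30.6 to 61.9 in the 4 HA libraries of induced cells, was 30.6 and 23.7 in the HA libraries without doxycycline, ran from 8.25 to 22.7 in the 6 IgG libraries and was 54.3 in the H3K27me3 library. A deeper library can call weaker peaks, so counts of peaks were also set side by side after thinning. In the thinning, the summit pileup and the window count of each peak were drawn binomially at the ratio of the depths, 20 times, and a peak was kept if its new −log10 p reached the lowest −log10 p of the shallower list. Tested on 5000 simulated peaks, the recovery returned 100% of the pileups, and thinning gave a called share of 85.9% where direct simulation at the lower depth gave 85.8%. Where fragments were spread along 5000 simulated peaks, so that the summit could move, thinning at the old summit called 0.90 to 0.94 times as many peaks as dropping fragments did, so thinned counts are somewhat low. This was simulated at a single ratio of depths. Thinning of the induced HA lists to IgG depth used lower ratios (0.202 to 0.482), where the shortfall was not measured. A thinned list also kept its own fragment length. The lengths were 161 to 172 bp in the induced HA lists, 152 and 108 bp in the uninduced HA lists and 104 to 166 bp in the IgG lists. What this does to the thinned counts was not measured.

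The 12 HA and IgG lists were merged into 71864 regions wherever intervals shared at least 1 bp. A region was taken as a site of a treatment if both of its HA lists had a peak there and none of the 8 control lists (the 2 HA lists without doxycycline and the 6 IgG lists) had one. Regions in both HA lists of one induced treatment and neither of the other were counted among those free of control peaks, and the same count was made for the other divisions of the 4 libraries into pairs. Numbers of peaks were compared with exact permutation tests, all two-sided. With 2 libraries against 2 the smallest p is 0.333, so those comparisons could not pass 0.05. Shares carry exact Clopper-Pearson intervals of 95%, which cover counting error only. Overlap with H3K27me3 peaks was set beside 100 seeded placements of the same sites at random within their chromosomes, between the first and last peak of any list. The labels do not say whether replicates came from separate cultures, so spreads between replicates may be technical.

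HA and IgG libraries of the same treatment and number came from the same nuclei, per the labels' protocols, and these pairs were used in the paired test. Over regions, the difference between replicates in the presence of a peak correlated between HA and IgG with r = -0.066 without doxycycline, -0.0059 with Myf6 and 0.014 with Myf6 and the compounds. Between treatments, replicates share a number and, in part, a name prefix. A prefix in the library names, whose meaning is not stated, is common to replicate 2 of all treatments, and another one to replicate 1 of both induced treatments, but replicate 1 without doxycycline carries its own. Values are therefore given within replicate numbers as well.

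The regions named in the text are the 10 with the best mean rank by the authors' q-value in each of 4 sets, a rule set before the data were examined. The rule had asked for the nearest genes of these regions. The gene table used here belongs to assembly GRCm38.p6 and the peaks to GRCm39, so no peak was assigned to a gene, and the planned comparisons of E-box and other motifs, of gene lists and of promoter shares were not run. Positions are therefore given as 1-based GRCm39 coordinates without gene annotation. Alternatives concerned the threshold on q, the overlap rule, peak extent, the control filter, list length and each replicate, and thinning to equal depth (also at stricter thresholds on q, with the matching p in the thinned list) and a filter on IgG peaks alone were added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.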

Results

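Binding of Myf6 was mapped in mouse embryonic fibroblasts with a doxycycline-inducible, HA-tagged Myf6. Myf6 (also MRF4) is a basic helix-loop-helix transcription factor of the myogenic family. The series asks where Myf6 binds during the conversion of fibroblasts towards muscle cells, and whether 3 compounds change that binding. Cells were kept for 24 h without doxycycline, with 2 µg/mL doxycycline (+Myf6), or with doxycycline, 5 µM Forskolin, 5 µM RepSox and 3 µM CHIR99021 (+Myf6+F/R/C). Forskolin activates adenylyl cyclase, RepSox inhibits the type I TGF-β receptor, and CHIR99021 inhibits the kinase GSK3. Each treatment had 2 HA and 2 IgG libraries, and H3K27me3 was measured in 1 library of +Myf6+F/R/C cells. Depth, as mean fragments per 10 kb, was 42.4 and 30.6 in the +Myf6 HA libraries and 61.9 and 40.9 in the +Myf6+F/R/C HA libraries (replicates 1 and 2). It was 30.6 and 23.7 in the HA libraries without doxycycline and lowest in the IgG libraries. Fold enrichments and q-values are the authors', and summit pileups are fragments over a summit as recovered from these.

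Induction of Myf6 was accompanied by about 10 times as many HA peaks. The +Myf6 HA libraries had 31809 ± 4769 peaks (mean ± SD, n = 2) and the HA libraries without doxycycline 3205 ± 1450 (n = 2), a ratio of 9.93 (3.31 on the log2 scale). The ratio was 13.1 within replicate 1 and 8.32 within replicate 2, and the lowest induced library had 6.72 times the peaks of the highest uninduced one. In +Myf6+F/R/C cells, 35244 ± 4540 peaks (n = 2) were found, 11.0 times the number without doxycycline. Peaks covered 0.685 ± 0.165 Mb without doxycycline, 10.3 ± 0.884 Mb with Myf6 and 13.2 ± 2.15 Mb with Myf6 and the compounds (n = 2 each). Neither comparison could pass 0.05 with 2 libraries against 2 (exact permutation p = 0.333 for both, the smallest possible). Thinned to the depth of the uninduced list of its number, the +Myf6 lists kept 22378 and 26697 peaks, 10.3 and 6.31 times the uninduced counts. The +Myf6+F/R/C lists kept 22675 and 20201 peaks, 10.4 and 4.78 times the uninduced counts, against 17.6 and 7.57 times before thinning. Thinning evened out the depth but not the fragment lengths, which were shorter in the uninduced lists.

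HA peaks also outnumbered IgG peaks from the same nuclei. The 4 induced HA libraries held 28436 to 38454 peaks and their 4 IgG libraries 437 to 1724. The mean log2 ratio was 5.15, a 35.6-fold difference, with the HA library higher in 4 of 4 pairs (exact permutation p = 0.0286, two-sided, n = 4 each, the smallest possible). With HA and IgG kept as pairs, exact sign flips gave p = 0.125, the smallest that 4 pairs allow. After thinning to the depth of the paired IgG library, the HA lists kept between 4.18 and 16.0 times the IgG count. Without doxycycline, HA peaks also outnumbered IgG peaks, by 5.03 times (exact permutation p = 0.333, n = 2 each). The ratios within replicates 1 and 2 were 4.39 and 5.44, and 3.48 and 4.48 after thinning. Part of the HA excess was thus present without induction.

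**Figure D1:**
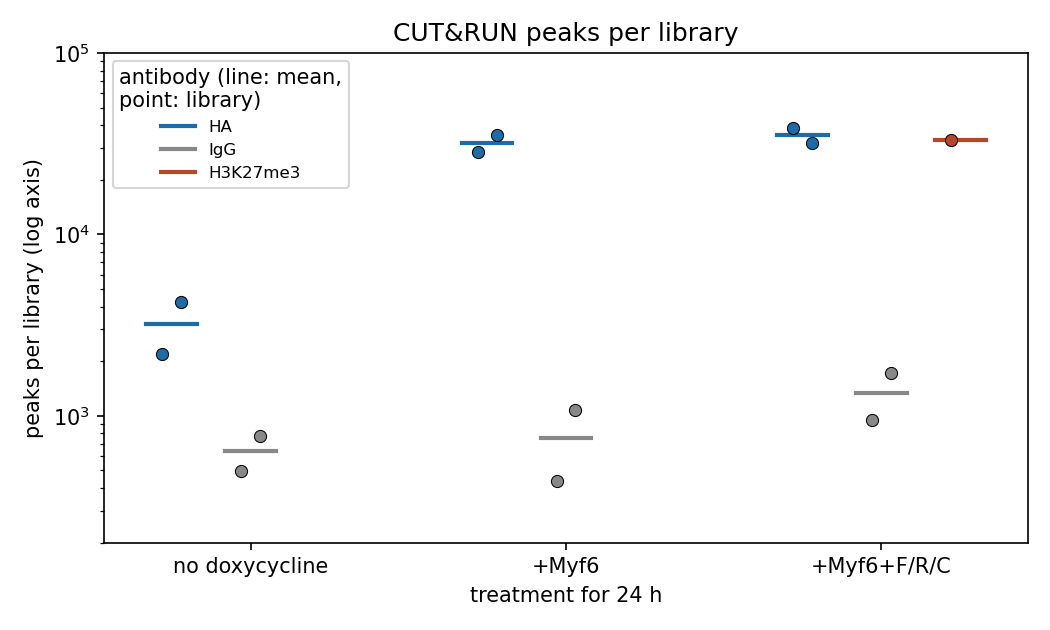
Peaks per library (log axis) by treatment and antibody; each point is a library and each line the mean of its group. HA libraries of induced cells lie between 28436 and 38454 peaks, HA libraries without doxycycline at 2179 and 4230, and IgG libraries between 437 and 1724.

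HA peaks without doxycycline lay mostly at places that also had an HA peak after induction, and so did IgG peaks of uninduced cells. Each uninduced HA list shared 60.3 to 87.2% of its regions with each induced HA list, and each uninduced IgG list 56.5 to 81.5%. Of 710 regions with a peak in both uninduced HA lists and no IgG list, 622 (87.6%, interval 85.0 to 89.9%) had a peak in all 4 induced HA lists and 8 had one in none. Taking each uninduced HA list by itself, again without IgG peaks, more regions had no induced peak. They were 157 of 1719 (9.13%) in replicate 1 and 846 of 3548 (23.8%) in replicate 2. The overlap grew with the strength of the induced peak. In the strongest decile of the induced HA lists, 37.2 to 43.3% of regions had an uninduced HA peak and 7.05 to 11.8% an IgG peak, and in the weakest decile 1.50 to 2.44% and 0.897 to 1.61%. Among the 100 strongest regions common to the 4 induced lists, 87 and 88 had a peak in the uninduced HA lists and 65 or 66 in each IgG list. The site definition, which leaves out every region with a control peak, thus removed 3286 of 15873 regions found in both +Myf6 lists and 3601 of 18690 found in both +Myf6+F/R/C lists, many of them among the strongest.

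**Figure D2:**
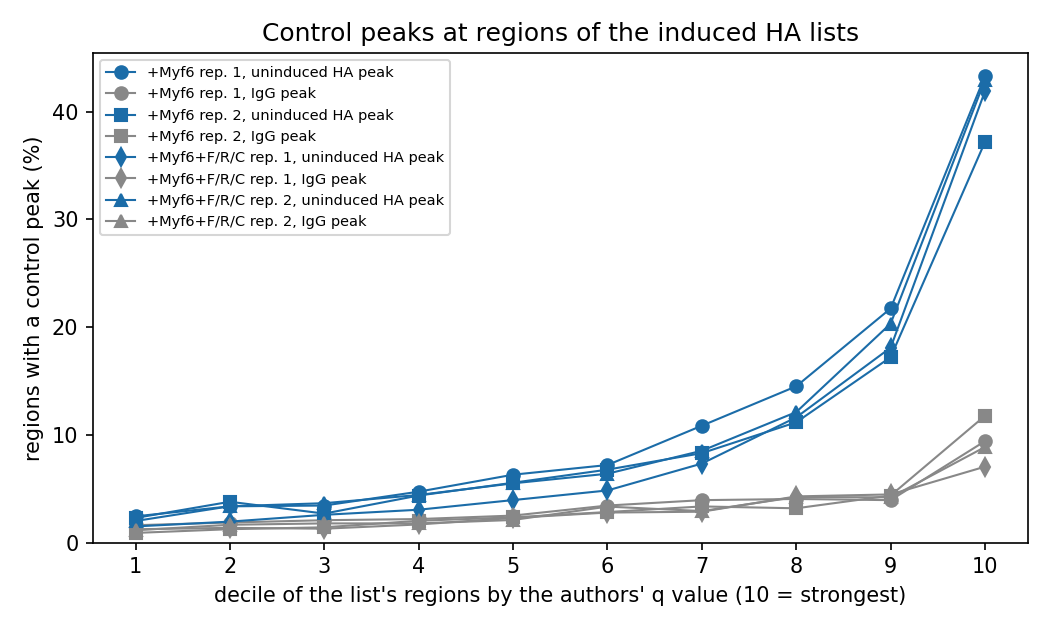
Share of the regions of each induced HA list that have a peak in any uninduced HA list (blue) or in any IgG list (grey), by decile of the list ordered by the authors' q-value; markers distinguish the 4 libraries. The share with an uninduced HA peak rises to between 37.2 and 43.3% in the strongest decile, and the share with an IgG peak to between 7.05 and 11.8%.

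With Myf6 alone, 12587 sites were found, with a median width of 575 bp. The site with the best mean rank lay on chromosome 9 at 94449483 to 94450680, with folds of 10.6 and 12.8 in replicates 1 and 2. It was followed by regions on chromosome 17 (12546667 to 12547325, folds 13.9 and 11.5), on chromosome 13 (37875882 to 37876813, folds 11.6 and 12.9) and again on chromosome 13 (58563221 to 58564092, folds 14.7 and 12.4). The fifth and sixth were on chromosome 14 (86773426 to 86774589) and chromosome 2 (49801249 to 49802048), with folds between 10.6 and 12.8. The last of the 10 were on chromosome 18 (10735269 to 10736732), chromosome 9 (114582024 to 114582824), chromosome 19 (56640129 to 56641135) and chromosome 3 (9254433 to 9255329). All 10 also had a peak in both +Myf6+F/R/C lists, and 5 had an H3K27me3 peak in +Myf6+F/R/C cells. Replicates shared most of the strong regions and fewer of the weak ones. Of the strongest decile of the +Myf6 replicate 1 list, 92.6% were in replicate 2, against 31.9% of the weakest decile; in the opposite direction the shares were 87.0 and 19.6%.

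With Myf6 and the compounds, 15089 sites were found, with a median width of 568 bp. The site with the best mean rank lay on chromosome 4 at 134238440 to 134239383, where folds were 11.5 and 14.2 in replicates 1 and 2 and summit pileups 62 and 57 fragments. In +Myf6 cells the same region had folds of 9.78 and 6.31. Next came regions on chromosome 2 (78019836 to 78020787, folds 10.7 and 9.18), chromosome 14 (86773426 to 86774589, folds 11.0 and 9.44) and chromosome 14 (79351880 to 79352835, folds 14.0 and 12.4). The region on chromosome 9 that led the +Myf6 sites was the fifth here, with folds of 9.18 and 10.2. The others of the 10 were on chromosome 1 (40894200 to 40894864), chromosome 3 (9254433 to 9255329), chromosome 7 (67034728 to 67035919), chromosome 9 (89549300 to 89550193) and chromosome 2 (49801249 to 49802048). Regions on chromosomes 2, 3, 9 and 14 made up the 4 that were among the 10 strongest of both treatments. Of these 10 sites, 1 had an H3K27me3 peak. Again 93.0% of the strongest decile of replicate 1 and 21.1% of the weakest were found in replicate 2.

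The treatments shared 7704 sites, which were 61.2% of the +Myf6 sites (interval 60.3 to 62.1%) and 51.1% of the +Myf6+F/R/C sites (50.3 to 51.9%). Independent lists of these lengths among the 64151 regions with an induced peak and no control peak would share 2961, though both lists were cleared of the same control peaks. Of the 64151 regions, 35797 were in 1 of the 4 induced lists only and could be a site of neither treatment. A pool without them would give a higher number, so 2961 is no firm reference for the sharing. Shared sites were wider, in part because they merge peaks of more lists, and had higher pileups than those of a single treatment. Their median width was 656 bp, against 423 bp for the 2809 regions in both +Myf6+F/R/C lists and neither +Myf6 list, and 377 bp for the 1613 regions in both +Myf6 lists and neither +Myf6+F/R/C list. Median summit pileups in the +Myf6+F/R/C libraries were 18 and 14 fragments at shared sites and 12 and 10 at the regions of that treatment alone. In the +Myf6 libraries they were 13 and 11 at shared sites and 9 and 8 at the regions of +Myf6 alone.

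At the deposited threshold, the difference in the number of HA peaks between +Myf6+F/R/C and +Myf6 cells was within the spread between replicates. The ratio of the means was 1.11 (0.15 on the log2 scale; exact permutation p = 0.667, n = 2 each), with 1.35 within replicate 1 and 0.911 within replicate 2. Among stronger peaks, both +Myf6+F/R/C libraries lay above both +Myf6 libraries. At −log10 q of at least 5 the ratios within replicates 1 and 2 were 1.57 and 1.14, and at 10 or more they were 2.40 and 1.55 (exact permutation p = 0.333 for both, the smallest possible with n = 2 each). The +Myf6+F/R/C libraries were also deeper than the +Myf6 libraries of their number. With their lists thinned to that depth, the ratios were 0.871 and 0.639 at 5 and 0.977 and 0.674 at 10. Regions of +Myf6+F/R/C alone outnumbered regions of +Myf6 alone by 1.74 times, by 3.41 times at −log10 q of at least 5 in every list (1881 and 551), and by 3.30 times with this threshold in the induced lists only. After thinning the ratio was 1.16 ± 0.011 at the deposited threshold and 0.342 ± 0.015 with the stricter one in the induced lists (SD of 10 draws). With the 4 lists at equal length it was 1.09. Within replicate 1 there were 18664 regions of +Myf6+F/R/C alone and 8908 of +Myf6 alone, and within replicate 2 there were 14762 and 17768. One-sided regions numbered 4422 between the treatments, 5582 between replicates 1 and 2, and 2800 in the remaining division. The mean depths of the sides were 51.4 and 36.5, 52.2 and 35.7, and 41.7 and 46.3 fragments per 10 kb, in this order. The larger counts thus belong to the divisions with the wider gaps in depth, and only the division by treatment was thinned. In overlap, 3 of the 4 libraries shared more of their regions with the same replicate number of the other treatment than with the other replicate of their own. The shares were 68.3 and 56.9% for +Myf6 replicate 1, 48.4 and 45.9% for +Myf6 replicate 2, and 50.1 and 49.2% for +Myf6+F/R/C replicate 1. For +Myf6+F/R/C replicate 2 they were 53.2 and 59.5%. These shares depend on the length of the other list. Taken as regions in both lists over regions in either, they were 33.9 and 34.1% for +Myf6 replicate 2, so its order reversed. The largest one-way share of that library, 51.5%, was with +Myf6+F/R/C replicate 1, which has the other number.

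**Figure D3:**
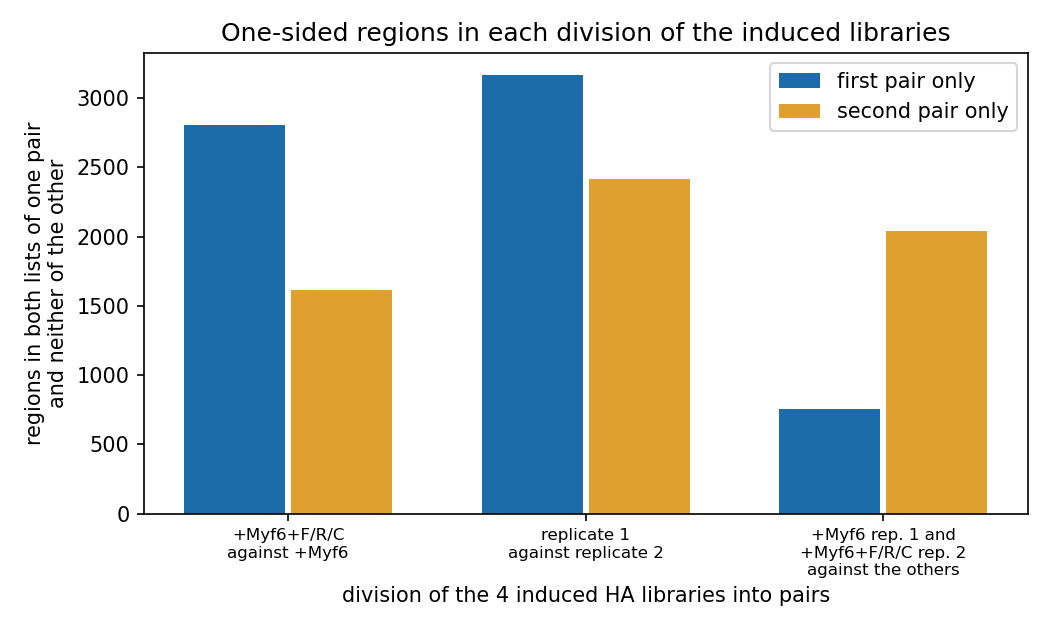
Regions with a peak in both lists of one pair of induced HA libraries and in neither list of the other pair, for the 3 ways to divide the 4 libraries into pairs (bars from 0). The division by treatment gives 2809 and 1613 regions, the division by replicate number 3167 and 2415, and the remaining one 758 and 2042.

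A few strong regions were found with one treatment only. With −log10 q of at least 10 in both lists of a treatment and no peak in either list of the other, 11 regions were particular to +Myf6+F/R/C and 3 to +Myf6. The same count was 23 and 2 for replicate 1 against replicate 2, and 0 and 3 in the remaining division. With the +Myf6+F/R/C lists thinned to the depth of the +Myf6 lists, a test added after the data were seen, the counts for +Myf6+F/R/C and +Myf6 were 1.9 ± 0.99 and 3.1 ± 0.32 (mean ± SD of 10 draws). When peaks under this threshold were disregarded in the other treatment too, 67.8 and 152.7 regions were left after thinning. The leading region of +Myf6+F/R/C alone was on chromosome 15 at 62468508 to 62469044, with folds of 10.4 and 9.89 and summit pileups of 33 and 23 fragments. Next were regions on chromosome 4 (131626026 to 131626837, folds 13.9 and 9.29), chromosome 9 (36827893 to 36828573, folds 9.08 and 8.76) and chromosome X (10018351 to 10019044, folds 9.96 and 8.76). The other 6 lay on chromosome 13 (30401597 to 30402244), chromosome 1 (90090129 to 90090747), chromosome 6 (144040556 to 144041067), chromosome 1 (56684555 to 56685144), chromosome 12 (100358483 to 100359134) and chromosome 1 (150650203 to 150650816). None of these 10 regions had an H3K27me3 peak. Of the regions of +Myf6 alone, the leading one was on chromosome 2 at 115405478 to 115405947, with folds of 11.1 and 10.4 and summit pileups of 21 and 16 fragments. It was followed by regions on chromosome 7 (130242577 to 130243069, folds 8.19 and 7.51), chromosome 8 (116256364 to 116256765, folds 8.24 and 9.37) and chromosome 16 (4931279 to 4931731, folds 8.09 and 8.04). The region on chromosome 8 had an H3K27me3 peak, the only one among the 10. The remaining 6 lay on chromosome 7 (49251209 to 49251617 and 138853287 to 138853537), chromosome 9 (116071081 to 116071695), chromosome 17 (25980614 to 25980865), chromosome 18 (5585302 to 5585590) and chromosome 15 (79298669 to 79299098).

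H3K27me3 peaks lay at about 32% of the Myf6 sites. The H3K27me3 library, which has no replicate, held 32981 peaks with a median width of 551 bp that covered 26.4 Mb. Of the 15089 +Myf6+F/R/C sites, 4881 overlapped an H3K27me3 peak (32.3%, interval 31.6 to 33.1%), against 1.86 ± 0.101% when sites were placed at random (SD of 100 placements, highest 2.09%). The share was 32.0% for +Myf6 sites, 34.7% for sites of both treatments, 28.0% for regions of +Myf6+F/R/C alone and 25.4% for regions of +Myf6 alone. Moved by 1 kb to either side, 9.70 and 9.52% of the +Myf6+F/R/C sites met an H3K27me3 peak, and moved by 2 kb 3.36 and 3.25%. Control peaks overlapped the mark as well, with 45.1% of the regions in both uninduced HA lists and no IgG list and 59.1 to 68.4% of the regions of 5 IgG lists. In the remaining IgG list, +Myf6+F/R/C replicate 2, which was the shallowest, the share was 31.0%, and over the 3156 regions of any IgG list it was 38.2%. Regions found in 1 list only had lower shares, 5.56 to 23.6% for the 6 IgG lists (17 to 976 regions each) and 17.7 and 26.0% for the +Myf6+F/R/C HA lists. In the opposite direction, 6382 of the H3K27me3 peaks (19.4%) lay at a site of either treatment. Their median summit pileup was 15 fragments, against 19 for the H3K27me3 peaks elsewhere, while the median fold was 5.59 against 5.27.

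**Figure D4:**
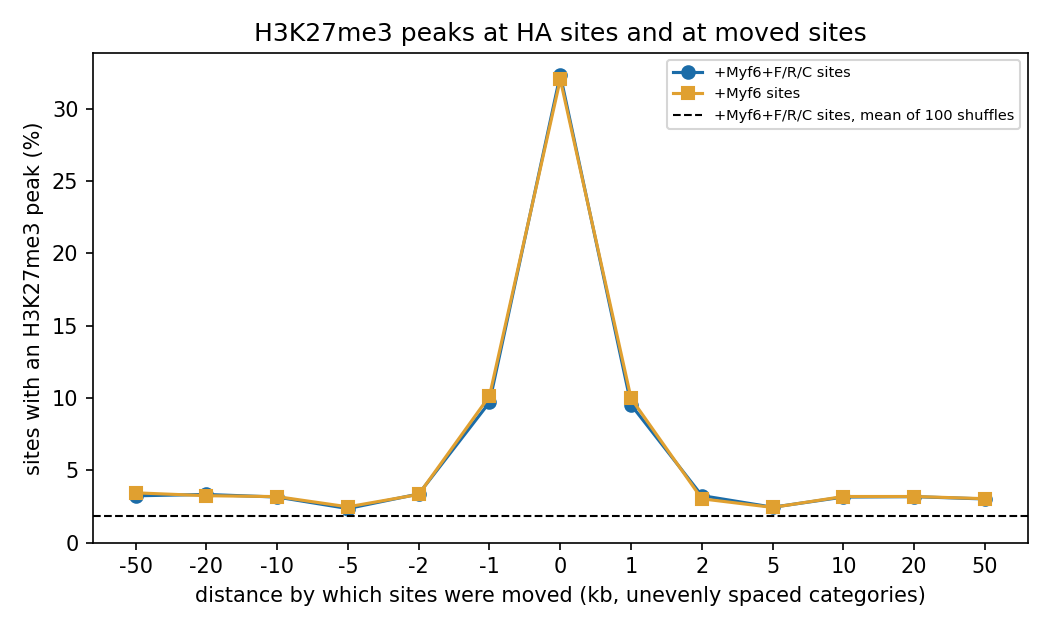
Share of +Myf6+F/R/C sites (blue) and +Myf6 sites (yellow) that overlap an H3K27me3 peak, at their own position and moved by 1 to 50 kb to either side; the categories on the horizontal axis are unevenly spaced and the dashed line is the mean of 100 random placements. The share falls from 32.3% at the +Myf6+F/R/C sites to 3.36 and 3.25% when these are moved by 2 kb.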

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

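Choices were fixed before the data were examined except thinning, alone or with a stricter threshold, and the filter on IgG peaks alone, which were added afterwards. The higher HA peak count with Myf6 than without kept its direction under all 8 alternatives (2.56 to 3.87 on the log2 scale, the lowest at −log10 q of at least 10), and its test could not pass 0.05 under any. With replicate numbers as a block the log2 ratio was 3.38. The difference between +Myf6+F/R/C and +Myf6 was positive under 9 of 11 alternatives but shrank to 0.0026 without +Myf6 replicate 1, 0.010 without +Myf6+F/R/C replicate 1 and 0.0024 after thinning, and was 0.45 and 1.04 at −log10 q of at least 5 and 10. Thinned and at these thresholds it was -0.40 and -0.23. Thinning holds each summit in place and so keeps too few peaks, 0.90 to 0.94 times the number in simulated peaks whose summit could move. The replicate block gave 0.15. Replicate differences of the 2 induced treatments correlated with r = 0.12 over regions. Their replicate numbers share a prefix in the library names, whose meaning is not stated. HA against IgG held at 5.15 in the paired test but no longer passed 0.05, as 4 pairs cannot, and without any 1 library it was 4.79 to 5.45, where the exact permutation p of 3 libraries against 4 was 0.0571, the smallest it can be. With pairs, the chromosome X difference between HA and IgG did not pass 0.05 either (exact sign flips, p = 0.125, n = 4 pairs).

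Counts of sites followed the threshold. At −log10 q of at least 5 in every list, 5007 +Myf6 sites, 7538 +Myf6+F/R/C sites and 551 regions of +Myf6 alone were left, and 1881 of +Myf6+F/R/C alone. With that threshold in the induced HA lists only, the counts were 3988, 6142, 517 and 1707. With a single replicate, which drops the need for a second peak, there were 24312 to 30863 +Myf6 sites, 27857 to 34068 +Myf6+F/R/C sites, 14762 to 18664 regions of +Myf6+F/R/C alone and 8908 to 17768 of +Myf6 alone. The overlap rule, summit windows, equal list length, both other control filters and thinning at the deposited threshold left each count within 1.5 times. Thinned at −log10 q of at least 5, 417 regions of +Myf6+F/R/C alone and 1219 of +Myf6 alone were left. The H3K27me3 share at +Myf6+F/R/C sites was 22.6% at −log10 q of at least 5 in every list, 36.1% without removal of control regions, 25.2 to 30.1% with a single replicate, and 32.4% with marks within 1 kb joined. The threshold also cut the H3K27me3 list, from 32981 to 23545 peaks, which can only lower the share. From the weakest to the strongest decile of the +Myf6+F/R/C HA lists, the share rose from 25.9 to 33.8% in replicate 1. In replicate 2 it rose from 28.0 to 41.3%. Beyond that, the cause of these shifts was not tested. Depth limits what a missing peak means, since the shallower libraries may hold sites under their threshold: after thinning there were 13275 +Myf6+F/R/C sites in place of 15089. The alternatives planned for motifs, gene lists and promoters were not run.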

Other observations

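Sites were spread unevenly over the genome. Over the span between the first and last peak of each chromosome, sites of either treatment numbered 7.52 per Mb in all, with 10.0 per Mb on chromosome 11, 9.61 on chromosome 19 and 9.18 on chromosome 15, against 1.64 on chromosome X and 0.033 on chromosome Y. Chromosome X held 1.60 ± 0.115% of the peaks of the 4 induced HA libraries and 4.03 ± 0.716% of those of their IgG libraries (exact permutation p = 0.0286, two-sided, n = 4 each; exact sign flips of pairs p = 0.125), a comparison chosen after the data were seen. The H3K27me3 library had 2.52% of its peaks there, and both uninduced HA libraries had 2.06 or 2.07%.

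Sites also occurred in clusters. Joined where they lay within 12.5 kb of each other, the 19972 sites of either treatment formed 16474 groups, 13668 of them single sites. There were 110 groups of at least 4 sites, against a mean of 17.4 and a highest of 25 in 100 random placements. The largest group in the random placements held 6 sites. No control list was grouped in the same way, so the excess is not shown to be particular to these sites. The largest observed groups held 7 sites each, on chromosome 6 (100140072 to 100173386) and on chromosome 12 (52865182 to 52915276). Groups of 6 lay on chromosome 5 (92634482 to 92654565 and 102916477 to 102951803), chromosome 7 (67912807 to 67944466) and chromosome 9 (58050604 to 58083780). On chromosome 9 all 6 were +Myf6+F/R/C sites and 4 were +Myf6 sites. IgG peaks had their own recurrent places: 265 regions were in all 6 IgG lists, 215 of these in all 12 lists, and 19 of the 265 lay on chromosome 9 between 3000026 and 3038268.

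The tests below were chosen after the pattern was seen, that of summit distance excepted. Thinning, which tests depth, was added after the data were seen. For depth and for summit distance the bounds were written before the values were computed. HA peaks without doxycycline lay at induced regions, and uninduced HA replicate 2 was set beside uninduced IgG replicate 1, of about the same depth (23.7 and 22.7 fragments per 10 kb). At 10525 of the regions in all 4 induced HA lists they had a peak at 18.9 and 2.11%, a ratio of 8.96. The whole lists differed about as much, with 4168 and 453 regions, and reached down to −log10 p of 4.51 and 5.49. The ratio is therefore not particular to these regions and is not matched for threshold. Thinned to the depth and lowest −log10 p of the uninduced IgG list of their number, the uninduced HA lists kept 1726 and 3482 peaks. These were 3.48 and 4.48 times the IgG counts. Of the 10625 regions in all 4 induced lists, 13.9 and 19.6% had an uninduced HA peak and 2.46 to 3.98% a peak in each IgG list. These values argue against cutting independent of the antibody as the whole source, outside the 100 strongest regions. At the 100 strongest regions the ratio of 1.35 (88 and 65 peaks) could not have exceeded 1.54. It leaves open whether cutting there depends on the HA antibody. Of the regions in both uninduced HA lists and no IgG list 1.13% lacked a peak in every induced list, but of those in uninduced HA replicate 1 or 2 and no IgG list 9.13 and 23.8% did. So HA-Myf6 signal without doxycycline, from expression or carry-over of fragments, stays open, as does binding of the HA antibody to something else at accessible places, and no biological explanation was tested.

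Regions of +Myf6+F/R/C alone outnumbered those of +Myf6 alone by 1.74 times. With the depth made equal by thinning, the ratio was 1.16, above the bound of a pure depth effect (1.1) and under the bound that would exclude depth (1.5), and at −log10 q of at least 5 it went from 3.30 to 0.342. At the deposited threshold the ratio lay between the bounds and thinning keeps somewhat too few peaks. Depth and an effect of the compounds therefore cannot be told apart for the excess that is left there. With the stricter threshold, thinning left a deficit in place of an excess (417 against 1219 regions), and the cause of this reversal was not tested. Counting the treatments themselves, 2 of the 3 divisions of the 4 libraries gave at least 4422 one-sided regions (highest other 5582, the division by replicate number), and 3 divisions are too few for a share under 0.05. Those 2 divisions also had the wider gaps in depth, so the divisions are not on an equal footing. An effect of the compounds on where Myf6 binds stays open and untested at this number of libraries.

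H3K27me3 peaks lay at HA sites more often than next to them. At 2 kb from the +Myf6+F/R/C sites, 10.2% of the share at the sites was left, which argues against a mere density of peaks in the neighbourhood. The share was at most 1.48 times as high in the strongest as in the weakest decile of a +Myf6+F/R/C HA list. Median summit pileups in these deciles were 32 and 8 fragments in replicate 1 and 24 and 6 in replicate 2. The ratio that carry-over of HA fragments into the H3K27me3 library would give was not derived. The deciles were also of whole lists, with regions that have control peaks, and not of sites. Carry-over therefore stays open. Summits of overlapping peaks lay a median of 181 bp apart in +Myf6+F/R/C replicate 2. With the H3K27me3 summit placed at random in its peak it was 195 bp, and 36.8 against 29.7% lay within 100 bp. Cutting at the bound position itself may therefore account for some of the overlap and stays open beside a narrow mark at the site. The share 2 kb away (3.36 and 3.25%) was about that 50 kb away (3.23 and 3.02%). The called narrow peaks thus give no sign of a mark that reaches far beyond the site. The H3K27me3 library is titled replicate 1, and summit distances to HA replicate 1 were not computed. Whether places where the nuclease cuts with any antibody add to the overlap stays open. Of the regions of any IgG list 38.2% had an H3K27me3 peak, against 5.56 to 23.6% of those in a single IgG list and no other list. These single-list sets held 17 to 976 regions and leave out every place that recurs in another list, so they cannot decide this. No biological explanation was tested.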
